A study of Mus musculus with 2 samples.

How the data were processed

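CTCF ChIP-seq peaks from newborn mouse lung were analysed, in 1 group of 2 replicates. Replicate numbers were taken from the labels, which give both the same biosample and donor. Any p-value below describes sites or genes in these libraries, and the spread between replicates may be technical.

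Per the labels, the authors' peak lists use the mm10 assembly. Per the deposited descriptions of the files, the list of each replicate was derived from that replicate's alignments and 1 further file whose role is not stated, and the labels name a possible control experiment. The pooled list came from both replicates, and the optimal and conservative lists are IDR-thresholded peaks made from the replicate and pooled lists. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here. The signal of each peak was deposited by the authors in column 7 of the list, and it is never negative. The −log10 of the q-value was deposited by the authors beside it, and it is at most 5.08 in the IDR lists. The score that the authors deposited in the IDR lists was not used. The position of the summit is an offset in bp from the peak start. Signals of the IDR lists are those of the pooled list, so values per replicate were taken from the highest peak of each replicate within 100 bp of the summit. The optimal and conservative lists share 56564 sites, and 8178 sites are in the first alone and 5495 in the second alone. The lists were not made for comparing samples, and signals were set side by side only to describe the spread between replicates.

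Sites on chromosomes 1 to 19 and X were used (64732 of 64742). Peaks on other contigs (10 in the optimal list) were left out. The reference genome was GRCm38, the assembly that mm10 names. Genes came from GENCODE release M21. A site was at a promoter when its summit lay within 1000 bp of the TSS of a protein-coding transcript, and otherwise it was assigned to coding exon, UTR, other exon, intron or intergenic sequence in that order. For gene lists, all TSSs of protein-coding transcripts of a gene were used, and those of all transcripts for non-coding genes. A promoter site can therefore lie inside a gene, far from its outermost 5′ end. Genes were counted by symbol, so annotated genes that share a symbol count as 1. The background was all other protein-coding genes.

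The core CCASYAGRKGGC was searched on both strands in a 101 bp window around the summit, with at most 1 mismatch, and in flank windows 1000 bp away. Orientation was taken from the strand with fewer mismatches, and sites with equal counts on both strands were left out. Overlaps were compared with 1000 circular shifts of the sites along each chromosome after the first 3000000 bp, and with 100 shifts for the shares of each annotated feature and for overlaps by bedtools. Shares have 95% Wilson intervals, which cover counting error only. The signal of promoter and other sites was compared by a permutation test with 100000 resamples, gene lists and motif shares by Fisher's exact test, gene clusters by permutation through the shifts, and orientation by an exact binomial test. Spearman's rho had a bootstrap interval from 200 resamples of sites. For GC content, 100000 sets of genes were drawn with replacement from the other protein-coding genes in the same of 20 GC bins. GC content was that within 500 bp of the outermost annotated 5′ end of each gene. A site at any TSS counted, and the number of TSSs per gene was not matched. All tests were two-sided at a threshold of 0.05, with Benjamini-Hochberg adjustment over the 15 lists and over the 13 clusters.

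Before the data were examined, the gene lists (lung epithelium, lung mesenchyme, endothelium, blood and immune, neuron, liver, heart and muscle, imprinted, cohesin and architectural, cell cycle, Hox, clustered protocadherins, ribosomal proteins, olfactory receptors, C2H2 zinc finger), the clusters and the rule for named genes were fixed. The rule names the 10 protein-coding genes with the strongest promoter site by mean rank in the 2 replicates (genes sharing a site count as 1, predicted names are skipped), the 3 members of each list with the strongest site, and Ctcf, Rad21, H19, Igf2, Sftpc, Nkx2-1 and Myc. Some genes that the rule selects are not reported here. Alternatives tried were the conservative list, the 32366 sites of highest signal, each replicate alone, other distances for summits (50 bp) and TSSs (500, 5000 and 25000 bp), other mismatch limits and windows, and gene clusters extended by 25000 bp. Dropping sites within 500 bp of a stronger site (1332 sites), using 1 TSS per gene, and the GC-matched draws with the 64732 highest peaks of each replicate alone were added after the data were seen.

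The measures were tested on simulated data. All of 5038 planted cores were found (100%) and the strand was recovered at 99.9% of 4990. A made overlap of 79.9% between replicates came out as 79.9%. In 50 simulated sets of sites over 21646 genes, with 40% of genes and 70% of a raised list bearing a site, the raised ribosomal list (79 genes) was called in 100% of runs, the raised cohesin list (26 genes) in 62%, and unchanged lists in 0.667% of list and run pairs. Adding 20 sites to the Pcdhg cluster in a uniform set gave a call for 1 of 13 clusters, Pcdhg. Simulated sites were placed uniformly and simulated genes drawn independently, so these rates need not hold for clustered sites or genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.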

Results

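Binding of CTCF was measured by ChIP-seq in lung tissue of newborn mice (postnatal day 0, strain B6NCrl). CTCF is a zinc finger protein that binds a long DNA motif, stops the movement of cohesin along chromatin and marks many boundaries of chromosome loops. There was 1 group with 2 replicates, numbered 1 and 2 in the labels. Both replicates cite the same biosample and donor, so the spread between them may be technical. No comparison group was analysed here, and the questions addressed were where CTCF was bound, at which genes, and how well the replicates matched. Each replicate had a list of 300000 peaks, and a list of the same length was made from both replicates pooled. The main list of sites was the authors' optimal list of 64742 peaks, thresholded by the irreproducible discovery rate (IDR). Of its 64732 sites on chromosomes 1 to 19 and X, 54063 had one of the 64732 highest peaks of both replicates within 100 bp, 777 had no peak of replicate 1 and 940 had none of replicate 2. The number of reads per replicate is unknown, because the lists carry none. The peak signal is the value the authors' peak caller gave each peak. Its scaling is not given in the sources used here. It was used to rank and describe peaks within a list.

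Among the CTCF sites that ranked highest over both replicates, the following were named after their values were seen. The peak at chromosome 5, positions 120102767 to 120103127 (mm10), lies between genes and had a signal of 327 in replicate 1 and 346 in replicate 2. A peak in a coding exon of Gdf15, a stress-induced cytokine of the TGF-beta superfamily, on chromosome 8 (70629725 to 70630132) had 326 and 332. An intronic peak in Pink1, a mitochondrial kinase, on chromosome 4 (138319538 to 138319896) had 318 and 316. A peak in a coding exon of Polr3gl, on chromosome 3 (96580186 to 96580539), had 341 and 309. Of the 64732 highest peaks of replicate 1 on chromosomes 1 to 19 and X, 55869 (86.3%, 95% Wilson interval 86.0% to 86.6%) had one of the 64732 highest peaks of replicate 2 within 100 bp. Over 1000 circular shifts of the replicate 2 positions along each chromosome, that share averaged 0.535% and reached at most 0.641%. Across 63131 sites with a peak in both replicates, Spearman's rho of the signals was 0.956 (bootstrap 95% interval 0.955 to 0.957). Sites are not independent replicates. These sites were kept by IDR thresholding, which can select for agreement between replicates. How far it did so here is unknown, since the sources do not describe in full how the optimal list was made. Sites in the optimal but not the conservative list had a median absolute log2 ratio of the replicates of 0.93. With the sites divided into 4 equal groups by pooled signal, the SD of log2(replicate 1 / replicate 2) was 0.13 in the highest group and 0.72 in the lowest. Over all 300000 peaks of each list, 36.8% of the peaks of replicate 1 had a partner in replicate 2, against a shifted mean of 2.45%.

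The sites of the main list carried the CTCF motif far more often than their surroundings. The core of the motif, CCASYAGRKGGC in IUPAC letters, was found with at most 1 mismatch within 50 bp of the summit at 31275 of 64732 sites (48.3%, 95% interval 47.9% to 48.7%). Windows of the same width centred 1000 bp to either side held it in 1658 of 129464 cases (1.28%, 1.22% to 1.34%). The p of Fisher's exact test (two-sided) was too small for double precision to hold. The share followed the signal. With all 64732 sites in 4 equal groups from highest to lowest signal, 70.2% (69.5% to 70.9%), 53.3%, 40.2% and 29.6% (28.9% to 30.3%) of sites had the core. The highest and lowest groups differed by 40.6 percentage points, again with a p of Fisher's exact test too small to hold. With no mismatch allowed, 12.4% of all sites had the core.

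**Figure D1:**
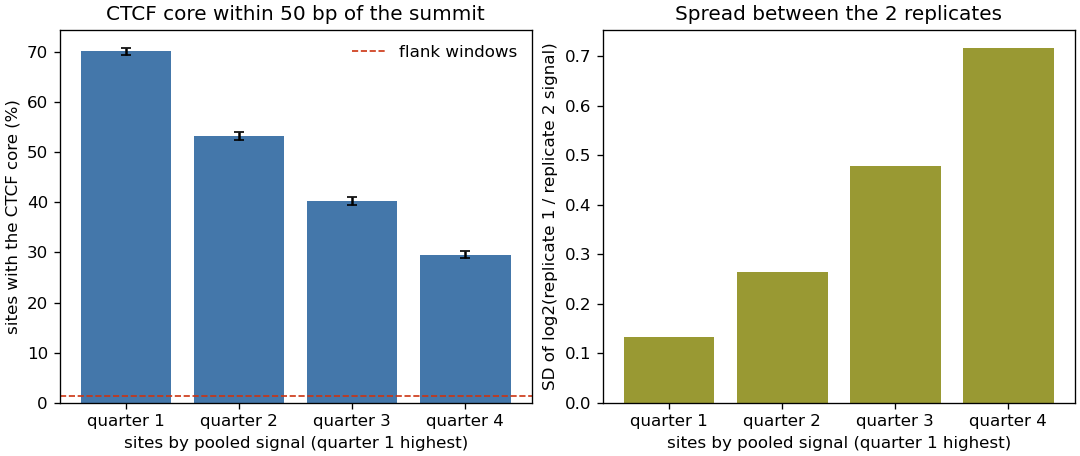
For 4 equal groups of sites by pooled signal, with group 1 highest, the left panel gives the percent of sites with the CTCF core within 50 bp of the summit (bars, with 95% Wilson intervals), falling from 70.2% to 29.6%, and the share in flank windows (dashed line, 1.28%). The right panel gives the SD across sites of log2(replicate 1 / replicate 2 signal), rising from 0.13 to 0.72. Its groups divide only the 63131 sites with a peak in both replicates, while those of the left panel divide all 64732 sites.

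CTCF sites were concentrated at promoters of protein-coding genes, and promoter sites had a lower signal than other sites. Of all sites, 10482 (16.2%, 15.9% to 16.5%) lay within 1000 bp of a protein-coding transcription start site (TSS), 6.18 times the mean of 2.62% over 1000 circular shifts (highest 3.06%). The strongest promoter sites lay at Gins4, a subunit of the GINS complex of DNA replication (chromosome 8, 23237706 to 23238039, upstream of the gene; signal 304 and 323 in replicates 1 and 2), at Pik3r2, a regulatory subunit of phosphoinositide 3-kinase (chromosome 8, 70769357 to 70769705, in an exon outside coding and UTR sequence; 301 and 291), and at Adprhl2, an ADP-ribose hydrolase (chromosome 4, 126321589 to 126321980, upstream of the gene; 287 and 319). Next came the site between the starts of Rab2b, a small GTPase, and Tox4 (chromosome 14, 52279294 to 52279629, in a UTR; 306 and 285). The others of the 10 strongest were at Twf2 (290 and 298), Acbd4 (284 and 301), Comtd1 (285 and 287), Nipsnap2 (275 and 315), Ddx47 (283 and 285) and Ccdc110 (294 and 270). The sites at Pik3r2, Twf2 and Acbd4 each lay more than 1000 bp inside the gene, near an annotated TSS other than its outermost 5′ end. The median log2 signal was 5.82 at 10482 promoter sites and 6.35 at 54250 other sites. The difference of -0.53 had p = 1e-05 in a two-sided permutation test, the smallest p that 100000 resamples can give. It was -0.33 with TSSs within 5000 bp and -0.18 among the 32366 sites of highest signal. Outside promoters, 2.32% of sites were in coding exons (shifted mean 1.21%), 1.956% in UTRs (1.34%) and 2.93% in other exons (1.84%), each above the shifted range. A further 43.2% were in introns (shifted mean 41.9%, within the shifted range) and 33.4% between genes (shifted mean 51.1%). The core motif was present at 20.6% of promoter sites, 38.9% of sites in coding exons, 52.7% of intronic and 56.2% of intergenic sites.

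The ribosomal protein genes, the clustered protocadherins and the list of cohesin and architectural genes had a CTCF site at their promoters more often than other genes, and olfactory receptor genes almost never had one. Of 21646 protein-coding genes, 8618 (39.8%) had a site within 1000 bp of a TSS. Among 15 gene lists fixed before the data were examined, 3 had a higher and 4 a lower share than all other protein-coding genes at an adjusted p below 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over the lists). The clustered protocadherins, cell-surface proteins whose promoter choice gives neurons individual identities, had a site at 40 of 56 genes (71.4%, 58.5% to 81.6%; adjusted exact p = 2.18e-05). Their strongest sites were at Pcdhgc3 (signal 132 and 117 in replicates 1 and 2), Pcdhgb6 (104 and 83.0) and Pcdhgb7 (90.9 and 86.9). The ribosomal protein genes had one at 52 of 79 (65.8%, 54.8% to 75.3%; adjusted exact p = 2.18e-05), among them Rps3a1 (219 and 233) and Rpl36 (217 and 207). Genes of cohesin and other architectural proteins had one at 18 of 26 (69.2%, 50.01% to 83.5%; adjusted exact p = 0.0119). Among them were Stag1, a cohesin subunit (202 and 206), Esco1, a cohesin acetyltransferase (176 and 176), and Pds5b, a cohesin regulator (157 and 183). The Stag1 site lay at an annotated TSS inside the gene (summit 100643576, gene 100597798 to 100959375 on the plus strand). With 1 TSS per gene the cohesin share was 65.4%, which still passed. Only 9 of 1092 olfactory receptor genes had a site (0.824%, 0.434% to 1.56%; adjusted exact p = 6.23e-228), the strongest at Olfr557 (142 and 124).

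Markers of blood, liver, and heart and muscle had a promoter site less often than other genes. Blood and immune markers had a site at 2 of 21 genes (9.52%, 2.65% to 28.9%; adjusted exact p = 0.0119), among them Mpo, the myeloperoxidase of neutrophils (69.5 and 74.5). The Mpo site lay at an annotated TSS inside the gene, and with 1 TSS per gene the blood and immune share was 4.76%. Liver markers had one at 3 of 20 (15%, 5.24% to 36.0%; adjusted exact p = 0.0487), namely Apob, an apolipoprotein (211 and 204), Ass1, an enzyme of the urea cycle (65.4 and 63.2), and Apoh (18.0 and 10.95). Heart and muscle markers had the same count and adjusted p, at Myl2, a ventricular myosin light chain (112 and 95.9), Ryr2, the calcium release channel of heart muscle (93.7 and 99.9), and Myod1, a regulator of muscle fate (15.3 and 17.4). The Myl2 site lay at an annotated TSS inside the gene. The liver and the heart and muscle calls ended with the conservative IDR list (15% of genes in each), without replicate 1 (15% and 25%) and at each other TSS distance tried, and the heart and muscle call also with 1 TSS per gene. With only the 32366 sites of highest signal, the calls of the protocadherins (21.4% of genes), cohesin, blood, liver and heart lists ended, as did those of the protocadherins and cohesin within 25000 bp of a TSS and of blood within 5000 bp. Within 25000 bp the blood (81.0%) and the heart and muscle (95%) shares turned to above the background, without a call. Draws matched for GC at the outermost 5′ end gave an expected 5.87 blood and immune, 6.06 liver and 14.3 cohesin genes with a site. The observed counts lay within the central 95% of draws (2 to 10, 3 to 10 and 9 to 19), those of blood and liver on the lower limit. Genes that share a cluster are not independent in Fisher's exact test, which concerns the protocadherins and the olfactory receptors most.

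For the remaining lists, the lung markers among them, no difference from other genes passed the threshold. Lung epithelial markers had a site at 12 of 28 genes (42.9%, 26.5% to 60.9%; adjusted exact p = 0.847). Within 5000 bp of a TSS their share was 82.1%, which passed. The strongest were at Abca3, the lipid transporter of surfactant-producing cells (chromosome 17, 24351775 to 24352051; 210 and 198), Muc1, a mucin (198 and 204), and Elf3, an epithelial transcription factor (175 and 139). Nkx2-1, the transcription factor of lung fate, had a weak site 694 bp from a TSS (6.45 and 13.5), and Sftpc, the gene of surfactant protein C, had its nearest site 3367 bp away. Lung mesenchymal markers had a site at 11 of 25 genes (44%; adjusted exact p = 0.736), with Gli1, an effector of hedgehog signalling (201 and 173), Col1a1 (166 and 179) and Pdgfra (164 and 165) highest. Endothelial markers had one at 5 of 20 genes (25%; adjusted exact p = 0.345; 40% without replicate 1 and 35% without replicate 2), with Esam (118 and 77.4), Egfl7 (72.4 and 83.5) and Erg (64.3 and 48.5) highest; Aplnr and Eng, named after their values were seen, were the others. Neuronal markers had one at 6 of 20 (30%; adjusted exact p = 0.571; 15% with the conservative IDR list), with Rbfox3 (217 and 203), Gad1 (69.99 and 80.3) and Syn1 (18.5 and 24.0) highest. The Rbfox3 site lay at an annotated TSS near the 3′ end of the gene (summit 118508082, gene 118489762 to 118911597 on the minus strand). That of Gad1 lay at a TSS inside the gene. The imprinted genes had one at 18 of 33 (54.5%; adjusted exact p = 0.162), with Mest (140 and 140), Grb10 (133 and 133) and Peg10 (108 and 108) highest. Their list, unlike the background, includes non-coding genes such as H19. Cell cycle genes had one at 14 of 30 (46.7%; adjusted exact p = 0.571), with Mcm5 (193 and 195), Ccna2 (136 and 136) and Mycn (131 and 138) highest. The Hox genes (9 of 39, 23.1%; adjusted exact p = 0.0616) and the Zfp genes of C2H2 zinc finger proteins (176 of 391, 45.0%; adjusted exact p = 0.0616, with Zfp638, Zfp398 and Zfp786 highest) did not pass the threshold either. Without replicate 2 both passed, and the Zfp genes also with TSSs within 500 bp. Ctcf itself had a promoter site with a signal of 26.1 and 46.5, the cohesin gene Rad21 one with 45.8 and 32.7, and Myc, the growth regulator, one with 70.7 and 69.4. The sites at Gli1, Pdgfra, Esam, Egfl7, Mest, Grb10 and Zfp638 each lay more than 1000 bp inside the gene. Each of these was near an annotated TSS other than the outermost 5′ end.

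**Figure D2:**
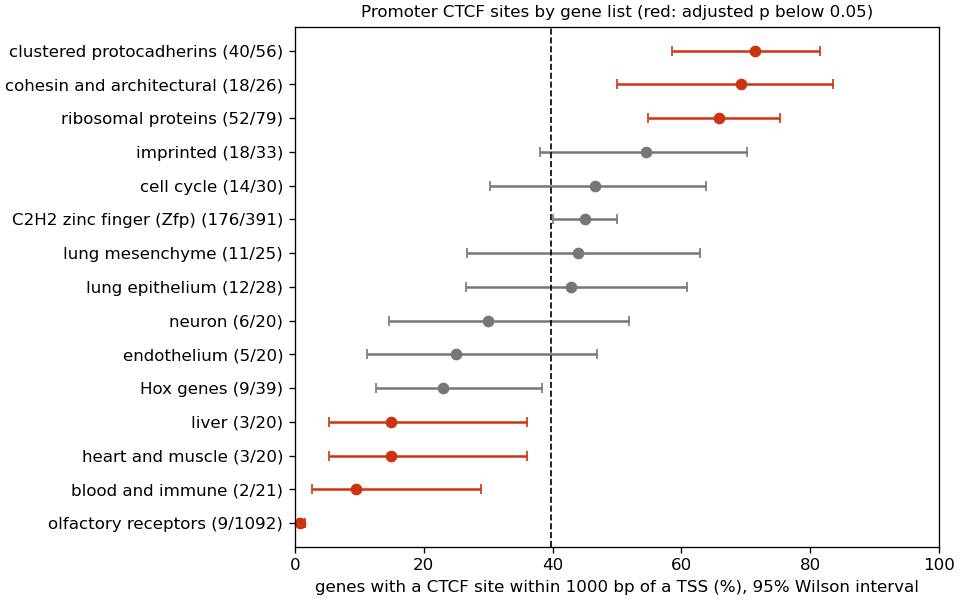
Percent of genes of each of 15 lists with a CTCF site within 1000 bp of a TSS (points, with 95% Wilson intervals, counts in the labels, red for an adjusted p below 0.05), and the share over all protein-coding genes (dashed line, 39.8%). The protocadherins are highest at 71.4% and the olfactory receptors lowest at 0.824%.

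The Hox, protocadherin and imprinted gene clusters held CTCF sites at and between their genes. The Hoxa cluster, transcription factors that pattern the body axis (chromosome 6, 52155590 to 52260880), held 10 sites. The strongest were at the starts of Hoxa7 (52221669 to 52221941; signal 209 and 204 in replicates 1 and 2) and Hoxa5 (52204478 to 52204798; 196 and 173), and Hoxb5 led its own cluster (187 and 178). The Hoxb, Hoxc and Hoxd clusters held 18, 5 and 7 sites. The Pcdhg cluster on chromosome 18 (37661793 to 37841873) held 22 sites, 18 of them at promoters, against a mean of 4.22 over 1000 circular shifts. The Pcdha and Pcdhb clusters held 7 and 17. In the imprinted H19-Igf2 region (chromosome 7, 142575529 to 142666816) 7 sites were found, of which 5 lay 1122, 2178, 2623, 3665 and 3864 bp upstream of the 5′ end of H19, a maternally expressed RNA. Without sites within 500 bp of a stronger site, the region held 5 sites, 3 of them in this stretch. The strongest of the region (142610648 to 142610856, 123 and 128) lay between H19 and Igf2, in an intron by the annotation, and Igf2, a fetal growth factor, had a promoter site with a signal of 30.2 and 20.2. The Igf2 site lay at an annotated TSS inside the gene. The Gnas, Kcnq1 and Dlk1-Meg3 regions held 8, 17 and 3 sites, the alpha globin cluster 1 and the beta globin cluster 0. Of the 13 clusters, 0 passed the adjusted threshold in the permutation test by circular shifts (two-sided, Benjamini-Hochberg), and 1 had an unadjusted p under 0.05. That was Pcdhg (permutation p = 0.0120, adjusted p = 0.156).

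**Figure D3:**
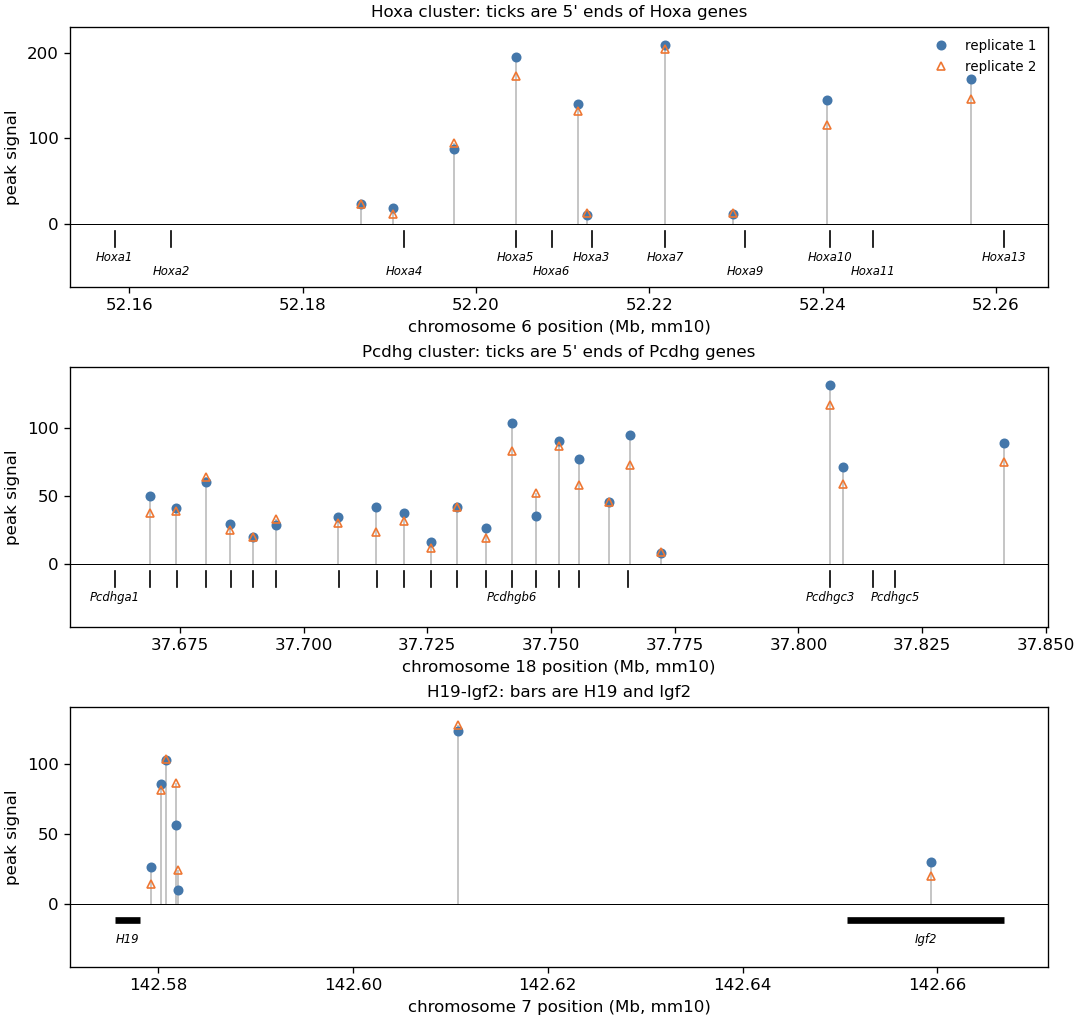
Sites in the Hoxa, Pcdhg and H19-Igf2 regions (mm10 positions in Mb) with the peak signal (no unit stated) of replicate 1 (filled circles) and replicate 2 (open triangles), ticks at the outermost annotated 5′ ends of Hoxa and Pcdhg genes, and bars over H19 and Igf2. The Pcdhg cluster holds 22 sites, and 5 sites lie within 5 kb upstream of H19.

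Neighbouring CTCF motifs lay on the same strand slightly more often than on opposite strands. Of 15714 pairs of neighbouring sites that each had 1 best core, 8292 (52.8%, 52.0% to 53.5%) were on the same strand (exact binomial test against equal shares, p = 4.09e-12). The cores of 3369 pairs (21.4%) faced each other and those of 4053 pairs (25.8%) faced apart. With no mismatch allowed the same-strand share was 52.4% (exact p = 0.104), which did not pass.

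The X chromosome had the lowest density of CTCF sites. It carried 1497 sites, or 8.75 per Mb, while the 19 autosomes ranged from 19.4 on chromosome 3 to 40.01 on chromosome 11, with a median of 26.1. The sex of the animals was not collected, and with 1 X chromosome no test was made. None of the lists held a peak on the Y chromosome, and whether they cover Y is not given in the sources used here.

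**Figure D4:**
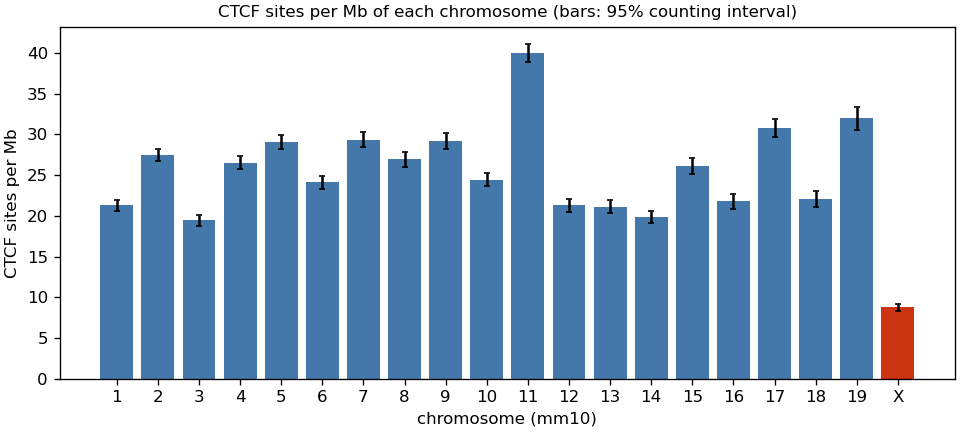
CTCF sites per Mb of each chromosome (bars, with 95% counting intervals). The X chromosome (red) has 8.75 sites per Mb, below all 19 autosomes (19.4 to 40.01).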

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

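The counts in this part were chosen after the main results had been seen, and no biological explanation was tested for them. A signal appeared in peaks outside the main list: of 178996 pooled peaks that were in neither IDR list and more than 2000 bp from a listed site, 7.99% (95% interval 7.87% to 8.12%) had the CTCF core within 50 bp of the summit, against 0.779% of their flank windows. Divided into 4 equal groups by signal, these peaks had the core in 18.4% of cases in the highest group and 2.92% in the lowest. On contigs outside chromosomes 1 to 19 and X, which the comparisons did not use, the optimal list held 10 sites, 5 of them on 1 unplaced contig. No expected count was set for these contigs, so this is a count above the limit that 0 counts allow (3) and no more.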

How the results depend on the processing

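Of 281 comparisons of a result with an alternative, 250 kept their direction and side of the threshold or stayed within their spread, 19 lost and 4 gained a call, 6 moved and 2 reversed. The motif share (12.4% to 76.2%), its fall with signal (24.4 to 40.9 points), the promoter share (12.3% to 30.4%) and the promoter signal difference (-0.53 to -0.18, the smallest with the sites of highest signal) kept their direction under every alternative run. The agreement of replicates ranged from 36.8% over all peaks to 94.7%, above the shifted values in each. With no mismatch allowed, the same-strand share was 52.4% (exact p = 0.104; 2.54e-25 to 0.0212 under the other alternatives), where fewer pairs were tested. The density on X fell to 4.50 sites per Mb with the sites of highest signal, which holds fewer sites by construction. The correlation of signals was 0.974 in the conservative list, 0.960 with summits within 50 bp, and 0.9504 as Pearson's r on log2 values. The number of gene lists past the threshold, 7, was 2 with the sites of highest signal and 2 with TSSs within 25000 bp, and 5 without replicate 1 and 9 without replicate 2. At 25000 bp, the blood and immune list (81.0%) and the heart and muscle list (95%) turned to a share above the background, both without a call. Within 5000 bp, lung epithelial markers reached 82.1% and passed the threshold. Without replicate 1 the liver and the heart and muscle lists lost their calls, and without replicate 2 the Hox and Zfp lists gained one, as did the Zfp list with TSSs within 500 bp (38.9%). With 1 TSS per gene, added after the data were seen, the heart and muscle list lost its call. The ribosomal and olfactory calls held under every alternative run. No cluster passed under any of them. The cause was not tested for the other changes. No paired analysis was possible because there is 1 group. Read depth is unknown, and the spread between replicates was widest at weak sites.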

Other observations

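The tests by spacing, the values by protocadherin family, repeats and IDR list, the GC draws for lists without a call and for each replicate alone, and the test of assembled sequence on X were chosen only after their results or closely related ones were seen. How neighbouring CTCF cores faced each other depended on their spacing. Among pairs on opposite strands 1 to 5 kb apart, 618 faced each other and 924 faced apart (40.1% convergent, 95% interval 37.7% to 42.5%; exact binomial test, adjusted p = 1.64e-14 over 5 spacings). Pairs 5 to 20 kb apart gave 41.0% (adjusted exact p = 8.29e-19). At 100 kb or more the direction was the opposite, with 404 convergent and 239 divergent pairs (62.8%, 59.0% to 66.5%; adjusted exact p = 1.32e-10). Below 1 kb and from 20 to 100 kb the shares were 48.3% and 48.4% and did not pass (adjusted exact p = 0.584 and 0.143). The highest peaks of each replicate alone gave 41.1% and 40.6% at 1 to 5 kb and 62.8% and 62.5% at 100 kb or more. Consecutive pairs can share a site, and in an unbroken run of sites convergent and divergent pairs alternate. Pairs and spacings are therefore not independent, although these binomial tests treat them so.

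The protocadherin families are given here side by side, and their difference was not tested. A site was present at 19 of 21 Pcdhg genes, 16 of 22 Pcdhb genes and 5 of 13 Pcdha genes (Pcdha6, Pcdha9, Pcdha11, Pcdha12 and Pcdhac1), counted by symbol, with 2 annotated genes under Pcdha11. The median signal of all sites in the cluster was 42.1 and 40.8 in replicates 1 and 2 for Pcdhg, 16.5 and 16.97 for Pcdhb, and 19.9 and 17.1 for Pcdha. The core with at most 1 mismatch was found at 1 site in each of the 3 clusters. Across the genome, 19.5% of summits lay in repeat-masked sequence (mean of 100 shifts 33.6%), where 68.0% had the core and the median signal was 51.6, against 43.5% and 88.6 in unmasked sequence. Sites in the optimal list alone had a median absolute log2 ratio of the replicates of 0.93, against 0.21 for those in the conservative list alone, with similar shares of the core (27.1% and 27.5%). Both lists were thresholded by IDR, so the difference in ratio can follow from how they were selected.

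Promoter sites held the CTCF core less often than other sites, at 20.6% (19.8% to 21.3%) against 53.7% (53.3% to 54.1%), and the highest peaks of each replicate alone gave differences of -33.1 and -33.1 percentage points. Lower signal at promoters was not enough to account for this, since within 20 bins of signal the weighted difference was -29.5 points. Secondary peaks beside a stronger site were also not enough, with -32.8 points when they were left out. A looser match to the core did not remove it, with -31.1 points at up to 2 mismatches after subtracting the flank share. At that limit 50.7% of promoter sites and 81.1% of other sites had the core (flank windows 9.30% and 8.56%). Signal from open chromatin at active promoters and recruitment of CTCF through other proteins may both remain, neither was tested, and the design gives no biological explanation to test.

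Whether a list had many promoter sites may follow from the GC content of its promoters, since the share of genes with a site rose from 1.08% in the lowest of 20 GC bins to 64.5% in the highest. GC was taken at the outermost 5′ end of each gene, while a site at any TSS counted. In random draws of genes matched for that GC, 5.87 blood and immune, 6.06 liver and 14.3 cohesin genes were expected. The observed 2, 3 and 18 lay within the central 95% of draws (2 to 10, 3 to 10 and 9 to 19). The blood and liver counts lay on the lower limit, and with so few genes the draws neither exclude nor establish GC as the cause. For 3 lists the draws argue against GC at that position as the whole cause, also with each replicate alone. Expected and observed counts were 10.4 and 40 protocadherins, 36.1 and 52 ribosomal protein genes, and 75.5 and 9 olfactory receptors. The draws treated genes as independent. Their ranges may therefore be too narrow for protocadherins and olfactory receptors, which share clusters. GC as the whole cause also stays open for heart and muscle, where 8.46 genes were expected and 3 observed (central range 4 to 13). The 5 observed without replicate 1 lay within the range of 5 to 13, and the 3 observed without replicate 2 lay outside that of 4 to 13. Among lists without a call, the 9 Hox genes observed lay below the central range of 13 to 24, the 176 Zfp genes lay 1 gene above that of 139 to 175, the 6 neuronal markers lay within theirs (5 to 13) but below it with each replicate alone (4 against 5 to 14 in each), and no biological explanation was tested.

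The low density of sites on X was set against 3 explanations. Less assembled sequence was excluded, since X had 9.16 sites per Mb of assembled bases and the lowest autosome 19.9. Exact copies of the core were sparser on X (2.95 per Mb, autosomes 3.45 to 7.23), but not as the whole cause, since X had 310 sites per 100 copies and the lowest autosome 452. The median signal at sites with an exact core was 142 on X, below the autosomes (214 to 280), while over all sites it was 78.995, within their range (69.6 to 84.0), so a lower signal that leaves more X sites under the threshold may contribute. Whether that signal follows from a single X chromosome in males remains untested, as the sex was not collected. No peak lay on the Y chromosome in any of the lists. Whether the authors' lists cover Y is not given in the sources used here, so this does not settle the sex.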
